A study of Mus musculus with 4 samples.

How the data were processed

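RNA libraries were made with the Illumina TruSeq protocol with index tags, per the labels' protocols, from 4 samples: 2 without and 2 with doxycycline (Dox). The design text describes the replicates as biological duplicates. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name TopHat and the mouse genome build mm9, without versions. The counting tool, its annotation and whether strand was used are not given in the sources used here.

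The deposited values are whole-number counts, 1 table per sample, for 208825 parts of genes. A part is named by 1 or several RefSeq transcripts and a part number, with no position. The layout is that of a count per exon part, in which a read that spans several parts may be counted in each, so the sum over a gene's parts can exceed its number of reads. Each table also has 4 rows that name no gene. These stayed out of library totals and tests. The row of reads outside genes corresponded to 13.6%, 15.8%, 14.5% and 15.5% of all counts in no Dox replicates 1 and 2 and Dox replicates 1 and 2, and that of ambiguous reads to 0.41% to 0.52%.

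Parts were summed to 21822 gene units. Names came from the RefSeq gene table of assembly GRCm38.p6 and from GENCODE M21, matched by transcript identifier. Of 27601 identifiers 98.1% matched, 21399 units had 1 symbol, 158 had several and 265 had none. Where 2 units shared a symbol, the one with the largest mean count stood for the gene. The reference is a later build than mm9, so no coordinates are given, and it was used only for names, neighbouring genes, exon order, exon lengths and annotated transcripts. Transcript identifiers are left out of the text, and genes are given by symbol.

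Part counts summed to 28239859 (no Dox replicate 1), 24020832 (no Dox replicate 2), 37311037 (Dox replicate 1) and 53903936 (Dox replicate 2). The most abundant gene, Col4a1, held 2.23% to 2.50% of them. Replicates differed by more than sampling noise (chi-square per degree of freedom 36.5 without and 32.6 with Dox), with a Pearson correlation of log2 CPM across genes of 0.986 and 0.991. Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersions, TMM scaling, the default filter on low counts and Benjamini-Hochberg adjustment at 0.05, which kept 14277 genes. The biological coefficient of variation was 0.148. The median log2 fold change of all genes was -0.01. CPM values are scaled by TMM and use the summed part counts as totals. For genes with 10 or fewer counts in both libraries without Dox together, the ratio of summed counts was given with its exact 95% interval, and against 0 counts a floor of 3 counts over the group was used. Intervals and floors cover counting error only.

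The comparison used 29 gene lists with 436 genes, fixed before the data were examined together with the test, the alternatives and the rule for named genes. Lists with at least 5 tested genes (26 lists) were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry. None of the 26 passed with an estimated correlation. The genes named are, first, Isl1 and Lhx3. Next come the 10 largest rises and up to 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and both Dox libraries on the same side of both others, passing over predicted genes without a name. Only 6 falls met this. Last come, per list, up to 4 called members with the smallest adjusted p or, with no call, up to 3 members with the largest mean CPM. A refused gene is left out and not replaced.

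On counts simulated for this comparison with the real means, dispersions and library sizes (14223 genes run), edgeR recovered 71% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, with 15 false calls. A list moved 2-fold as a whole was called with the preset correlation (adjusted p = 3.28e-60) and missed with the estimated one (adjusted p = 0.0766). No other list was called either way. With an estimated correlation the test has only the few degrees of freedom that 4 libraries leave. A list that misses with it may therefore still have moved. Genes were drawn independently in the simulation, so it cannot show how often correlated genes give false list calls. It also held no effect shared by libraries of the same replicate number, so its recovery rates need not hold for the real counts. In the real data the estimated correlation ran from -0.111 (neural crest markers) to 0.502 (Hox genes).

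Differential use of parts within genes was tested with edgeR on 129524 parts of 11556 genes, a step chosen after seeing the data. On simulated counts its gene-level F test found 193 of 200 genes whose parts from the sixth on rose 4-fold, with 43 false calls. Its Simes test found 174 with 12 false calls (11503 genes run). The simulated parts of a gene were drawn independently of each other. These rates need not hold for the real counts, where the F test gave fewer small p-values than expected with no effect.

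Alternatives were DESeq2 size factors, library totals alone, no filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, each library left out in turn, summing units that share a symbol, and a threshold of 0.01. With 1 library of a group left out, the remaining one is assumed to vary like the other group. Chosen after seeing the data were thinning all libraries to the smallest total and taking the largest part of each gene as its count. Some genes that the naming rule picked are not reported here; they stayed in the fits and list tests and were left out of the comparison of alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.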

Results

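RNA was sequenced from cell aggregates grown from mouse iMN-ESCs, an embryonic stem cell line in which doxycycline (Dox) switches on a fusion of Isl1 and Lhx3. These are LIM-homeodomain transcription factors present together in spinal motor neurons. Aggregates were kept for 2 days in stem cell medium and for 2 days in 0.5 µM all-trans retinoic acid, and then for another 2 to 3 days in retinoic acid either with 2 µg/mL Dox or without it. Each of the 2 groups held 2 libraries. Counts assigned to parts of genes summed to 28239859 and 24020832 in the libraries without Dox, and to 37311037 and 53903936 in the libraries with Dox. The design implies 1 comparison, with against without Dox, which asks which genes of the motor neuron and interneuron programs change with Dox. No group received Dox without the transgene, so effects of the fusion and of Dox itself cannot be told apart.

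The fused factors were read in every library first. Lhx3 stood at 0.404 and 0.286 CPM (counts per 1000000) without Dox and at 125 and 108 CPM with Dox, a log2 fold change of 8.37 (SE 0.22, adjusted p = 0.00028). Isl1 stood at 3.08 and 5.84 CPM without Dox and at 104 and 82.4 CPM with Dox, a log2 fold change of 4.39 (SE 0.31, adjusted p = 0.00351). Both therefore followed the labels of all 4 libraries. With the largest part of each gene as its count, an alternative chosen after seeing the data, the changes were 7.24 for Lhx3 and 5.02 for Isl1. The counts do not separate transcripts of the fusion from those of the cells' own Isl1 and Lhx3 genes. The rise per kb differed between parts of the genes, although the test of part use called neither Isl1 (adjusted p = 0.582 by F and 1 by Simes) nor Lhx3 (1 by both). In Isl1, the part that holds the last exon rose by 9.25 CPM per kb, against 58.2 to 145 CPM per kb in the parts that are wholly coding. In Lhx3 it rose by 33.4 CPM per kb, against 85.8 to 110 CPM per kb.

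Of 14277 genes tested, 175 were higher and 8 were lower with Dox at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 167 were at least 2-fold higher and 6 at least 2-fold lower. At an unadjusted p under 0.05, 893 genes were higher and 573 lower. In all 183 called genes both libraries with Dox lay on the same side of both libraries without Dox. Over all genes tested 38.8% did so, and chance gives 33.3%. Calls made from these same values favour such genes, so the separation is not independent support for the calls. The counts depended on the libraries: 276 genes were higher and 24 lower without no Dox replicate 1, 278 and 84 without no Dox replicate 2, 284 and 124 without Dox replicate 1, and 276 and 22 without Dox replicate 2. DESeq2 called 398 genes higher and 113 lower. A fit with the replicate number as a block called 1046 higher and 864 lower, so the small number of falls depended on the model.

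Beside Lhx3, the 10 largest rises among genes with a mean of at least 5 CPM held 4 genes of acetylcholine handling, described below, and 5 others. Ecel1, a membrane metalloprotease of neurons, rose from 1.98 and 2.29 CPM to 175 and 249 CPM (log2 fold change 6.64, SE 0.25, adjusted p = 0.00065). Cbln2 and Cbln1, secreted synapse organisers, rose by log2 6.15 (SE 0.20, adjusted p = 0.000443) and 4.97 (SE 0.29, adjusted p = 0.0019). Arhgap36 rose from 2.61 and 2.41 CPM to 97.4 and 177 CPM, and Rasgef1c from 0.991 and 0.816 CPM to 37.2 and 51.3 CPM. Falls were smaller. Lgr5, a receptor for R-spondins, fell from 32.5 and 30.4 CPM to 10.7 and 8.97 CPM (log2 fold change -1.68, SE 0.16, adjusted p = 0.00831). Pou4f1, a POU-homeodomain factor of sensory neurons and dorsal interneurons, fell by 1.49 on the log2 scale (SE 0.15, adjusted p = 0.00906). Nmnat2, which makes NAD in axons, fell by 1.91 (SE 0.21, adjusted p = 0.0156). Ndnf, a secreted neuronal factor, fell from 23.0 and 25.7 CPM to 9.47 and 7.82 CPM (adjusted p = 0.0183). Aldh1a7 and Crabp1 fell by 0.97 (adjusted p = 0.0403) and 0.84 (adjusted p = 0.0479). Both calls sat close to the threshold. The call for Crabp1 ended without Dox replicate 2 (adjusted p = 0.156) and with DESeq2 size factors (adjusted p = 0.0513), and that for Aldh1a7 ended with library totals as the only scaling (adjusted p = 0.0509). Both also ended when only genes with a mean of 5 CPM were tested (0.0716 for Crabp1 and 0.0604 for Aldh1a7), and that for Aldh1a7 with the largest part as its count (0.163).

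**Figure D1:**
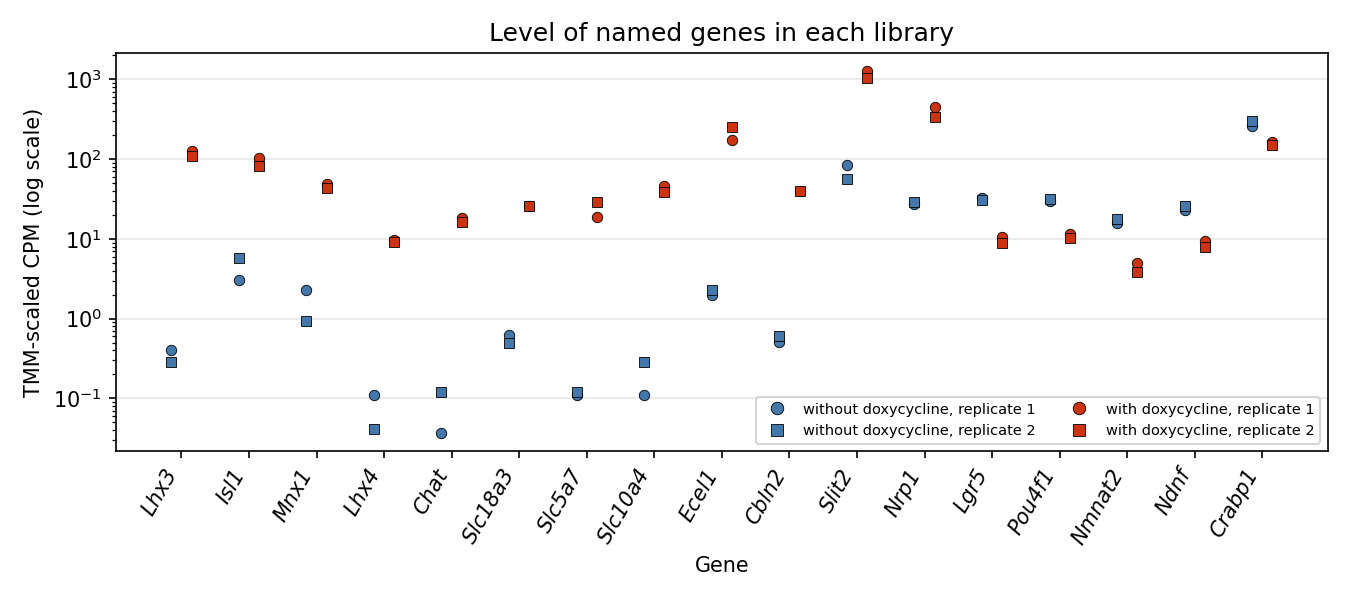
TMM-scaled CPM, on a log scale, of 17 named genes in each of the 4 libraries; blue marks libraries without Dox, red those with Dox, and circles and squares are replicates 1 and 2. Lhx3 lay at 0.404 and 0.286 CPM without Dox and at 125 and 108 CPM with it, and Lgr5 at 32.5 and 30.4 CPM without Dox and at 10.7 and 8.97 CPM with it.

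Steep rises were seen in 4 genes of acetylcholine synthesis and transport. Of 8 cholinergic genes, 4 were higher, none was lower and 4 were not called. Adjusted over the list alone, 4 were higher and 1 lower, as at an unadjusted p under 0.05 and without Dox replicate 1. Chat, which makes acetylcholine, went from 0.037 and 0.122 CPM to 18.1 and 16.4 CPM (log2 fold change 7.74, SE 0.37, adjusted p = 0.000968). Slc18a3, its vesicular transporter, went from 0.624 and 0.49 CPM to 25.7 and 25.5 CPM (5.51, SE 0.22, adjusted p = 0.00065). It lies inside the Chat gene, so reads of the pair may not be fully separated. Slc5a7, the choline transporter, and Slc10a4, found on cholinergic vesicles, rose by log2 7.63 (SE 0.41, adjusted p = 0.00161) and 7.74 (SE 0.32, adjusted p = 0.000751). Control counts were low: Chat had 4 counts in both libraries without Dox together against 1572 with Dox, a ratio of 221 (95% counting interval 86.2 to 812), Slc5a7 had 6 against 2261 (ratio 212, 97.2 to 578) and Slc10a4 had 10 against 3817 (ratio 215, 117 to 448). The size of the Chat change moved with them, to log2 7.11 without no Dox replicate 1 and 8.76 without no Dox replicate 2, and that of Slc10a4 to 8.54 without no Dox replicate 2. Ache, the esterase, stood at 2.20 and 3.92 CPM without Dox and 2.84 and 2.86 CPM with it (adjusted p = 0.981). In the list 4 members lay above 0 and 4 below 0, with the median log2 fold change of 2.70 between them. The median was 6.58 when only genes with a mean of 5 CPM were tested. The list was higher than other genes (camera adjusted p = 1.81e-38, and 0.137 when the correlation between genes was estimated). The estimated correlation was -0.0519, below the preset 0.01, so correlation between its genes does not explain the higher p. As a set moving one way, the list had a fry p of 0.000706. Of the other 10 lists that camera called, fry gave an unadjusted p of 0.0179 to 0.0439 for 5, and did not pass for axon guidance (0.0705), dorsal interneuron (0.0763), heat shock (0.102), Notch (0.308) and neural progenitor genes (0.359).

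Among 17 motor neuron transcription factors, edgeR called 3 higher, none lower and 14 neither way. Beside Mnx1, Lhx4 and Lmo4 the list held Isl2, Nkx6-1, Zfp503, Tshz1, Onecut1, Onecut2, Onecut3, Ebf1, Ebf2, Ebf3, Neurod1, Neurod4, Nhlh1 and Nhlh2. Whether each is confined to motor neurons was not tested, so the list does not measure motor neuron identity alone. Adjusted over the list alone, as at an unadjusted p under 0.05, 4 were higher and 8 lower. DESeq2 called 3 higher and 6 lower, and limma-voom 3 higher. The edgeR test called 4 lower without Dox replicate 1, 2 lower without no Dox replicate 2 and 1 lower without either other library. Mnx1 (Hb9), a determinant of motor neuron identity, went from 2.31 and 0.939 CPM to 48.5 and 43.9 CPM (log2 fold change 4.81, SE 0.36, adjusted p = 0.00394). Without no Dox replicate 1 the change of Mnx1 was 5.62. Lhx4, the close relative of Lhx3, went from 0.110 and 0.041 CPM to 9.61 and 9.08 CPM (6.86, SE 0.39, adjusted p = 0.00161), which rests on 4 control counts (ratio 120, 95% counting interval 46.8 to 442). Without no Dox replicate 1 the change of Lhx4 was 7.74. Lmo4, a LIM-only cofactor, rose by log2 1.31 (SE 0.18, adjusted p = 0.0342), a call that ended when only genes with a mean of 5 CPM were tested (adjusted p = 0.0526). The median of the list was -0.45 and its mean 0.27; the median was -0.14 without Dox replicate 2 and -0.71 without Dox replicate 1. The set test gave an adjusted p = 0.96, and 0.986 with an estimated correlation. Over the 12 members with a mean of 5 CPM, which leaves out Lhx4, Isl2, Onecut1, Onecut3 and Nkx6-1, the list was lower (median -0.89, adjusted p = 0.0211; adjusted p = 0.793 with an estimated correlation).

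Genes of motor neuron columns and pools were higher as a list (camera adjusted p = 0.00016; adjusted p = 0.456 with an estimated correlation), with 2 of 12 tested members called higher by edgeR and by limma-voom, and 3 higher and 1 lower by DESeq2 and by edgeR without Dox replicate 1. The numbers adjusted over the list alone were 5 higher and 2 lower. The median of 0.39 became 0.76 without no Dox replicate 1, 0.16 without no Dox replicate 2, 0.20 with no filter, 0.10 over genes with a mean of 5 CPM and 0.21 in DESeq2. Mecom (Evi1) rose by log2 1.90 (SE 0.15, adjusted p = 0.004). Chodl, a marker of fast motor neurons, had 4 control counts and rose to 5.22 and 9.26 CPM (ratio 98.6, 95% counting interval 38.3 to 363, adjusted p = 0.00758). Its log2 change of 6.49 became 5.86 without no Dox replicate 1 and 7.51 without no Dox replicate 2. Among 7 tested genes of cranial and visceral motor neurons, the T-box factors Tbx2 (log2 fold change 3.05, SE 0.24, adjusted p = 0.00442) and Tbx20 (2.15, SE 0.29, adjusted p = 0.0305) rose. That list had a mean of 0.38 and a median of -0.30, and its set test, in the direction of a rise, gave an adjusted p = 0.0494 (0.456 with an estimated correlation). Its median was -0.13 and -0.15 without no Dox replicates 1 and 2, and -0.14 and -0.48 without Dox replicates 1 and 2. This call ended without any one of the 4 libraries, with an adjusted p between 0.0502 and 0.204, and also with library totals (0.0659), no filter (0.115) and limma-voom (0.741).

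Axon guidance receptors and ligands had the most called members of any list, with 8 of 31 higher and none lower. Adjusted over the list alone, 9 were higher and 4 lower. DESeq2 called 8 higher and 3 lower, limma-voom 8 and 1, and at an unadjusted p under 0.05 the numbers were 11 and 4. In edgeR 4 were lower without Dox replicate 1, 3 without no Dox replicate 2 and 1 without either other library. Slit2, a secreted ligand of Robo receptors, reached 1268 and 1048 CPM from 84.1 and 56.5 CPM (log2 fold change 4.04, SE 0.25, adjusted p = 0.00218). Slit3 rose by log2 2.79 (SE 0.13, adjusted p = 0.000968). The semaphorin receptor Nrp1 rose from 27.7 and 29.1 CPM to 449 and 340 CPM (3.79, SE 0.18, adjusted p = 0.000968), and the netrin receptor Unc5c by log2 1.81 (SE 0.16, adjusted p = 0.0071). The list was higher than other genes (camera adjusted p = 5.6e-15, median 0.40; adjusted p = 0.456 with an estimated correlation). Its median was 0.21 without no Dox replicate 2 and 0.22 without Dox replicate 1. In both Slit genes the change differed along the transcript. The first 4 parts of Slit2 differed by 0.55 on the log2 scale (counting interval 0.40 to 0.71), part 5 by 1.91, and those from part 6 to the last by 4.20. The interval leaves out replicate spread. These first 4 parts summed to 12.3 and 5.84 CPM without Dox and to 19.8 and 9.35 CPM with Dox, so the groups overlapped. In Slit3 the first 4 parts differed by -0.01 (counting interval -0.45 to 0.44), part 5 by -0.25, and those from part 6 on by 2.88.

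**Figure D2:**
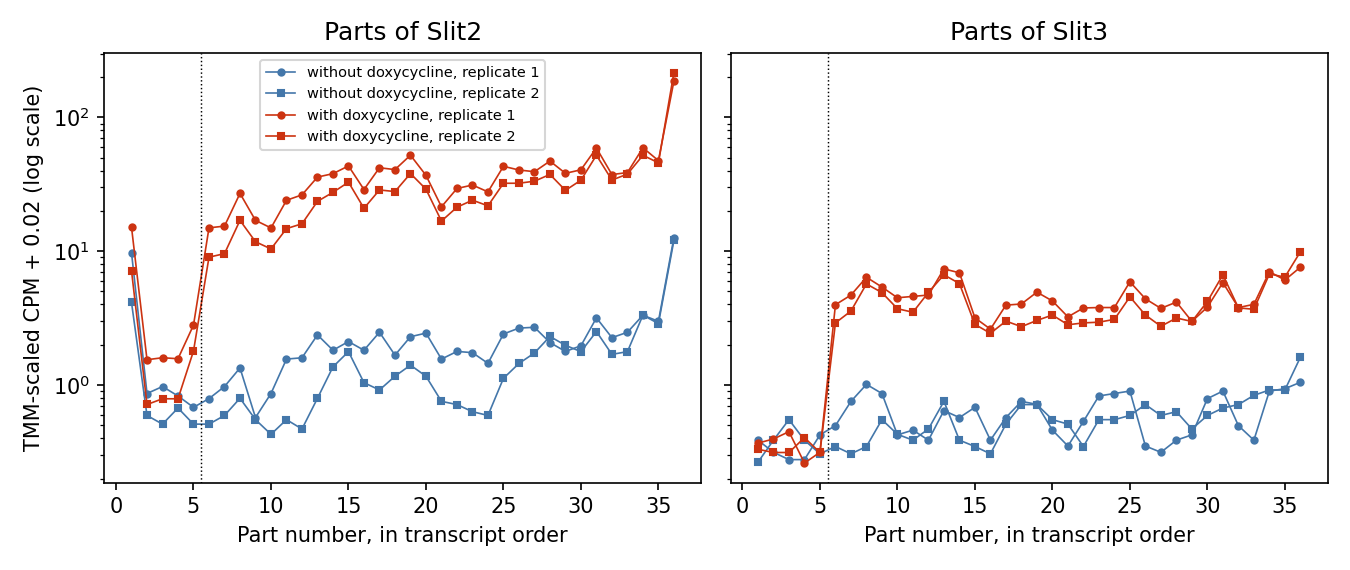
TMM-scaled CPM plus 0.02, on a log scale, of the 36 parts of Slit2 (left) and Slit3 (right) in transcript order, 1 line per library; red lines are libraries with Dox, blue lines those without, and the dotted line lies between parts 5 and 6. Red and blue lines run together over the first parts of Slit3 and apart from part 6 on.

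Of 3 interneuron lists, 2 were lower with Dox at the preset correlation and none at an estimated one (adjusted p = 0.456 for each), with few single calls. Of 6 V2 interneuron genes tested, none was called by edgeR, limma-voom or DESeq2, and 2 were lower at an unadjusted p under 0.05. Sox21 stood at 10.8 and 11.8 CPM without Dox and 7.14 and 7.21 CPM with it (adjusted p = 0.221), Bhlhe22 had a log2 fold change of -0.71 (SE 0.28, adjusted p = 0.45), and Gata3 one of 0.12 (SE 0.22, adjusted p = 0.949). The V2 list had a median of -0.52 and a set test adjusted p = 0.102 (0.456 with an estimated correlation). Without Dox replicate 1 that p was 0.0343 (0.530 with an estimated correlation). Of the 10 list members, 4 had too few counts to be tested. Of 10 tested V0, V1 and V3 interneuron genes, 0 were called by edgeR in the main test. At an unadjusted p under 0.05, 8 were lower, and 6 were lower when adjusted over the list alone. With the replicate number as a block, edgeR called 7 lower and 0 higher. DESeq2 called 3 lower and limma-voom 1, and edgeR 4 without Dox replicate 1 and 2 without no Dox replicate 2. Dbx1, a factor of V0 progenitors, stood at 49.6 and 43.9 CPM without Dox and at 25.3 and 18.5 CPM with it (log2 fold change -1.09, SE 0.18, adjusted p = 0.064). Dbx1 passed the threshold without no Dox replicate 2 (adjusted p = 0.0206) and without Dox replicate 1 (0.00116). Pax2 had a log2 fold change of -1.39 (SE 0.39, adjusted p = 0.245; 0.0007 without Dox replicate 1). The list was lower than other genes (camera adjusted p = 1.61e-07, median -1.16; adjusted p = 0.456 with an estimated correlation). Dorsal interneuron genes, 1 of 15 called (Pou4f1, above), were also lower as a list (camera adjusted p = 3.64e-06, median -0.73; adjusted p = 0.456 with an estimated correlation). Adjusted over that list alone, 1 gene was higher and 7 were lower, DESeq2 called 3 lower, and edgeR 1 to 4 with a library left out. None of 9 excitatory and inhibitory transmitter genes was called by edgeR, DESeq2 or limma-voom. Gad2 and Slc6a9 had log2 fold changes of 0.23 and 0.09. The transmitter list had a median of 0.02 and a mean of -0.10 (set test adjusted p = 0.549).

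**Figure D3:**
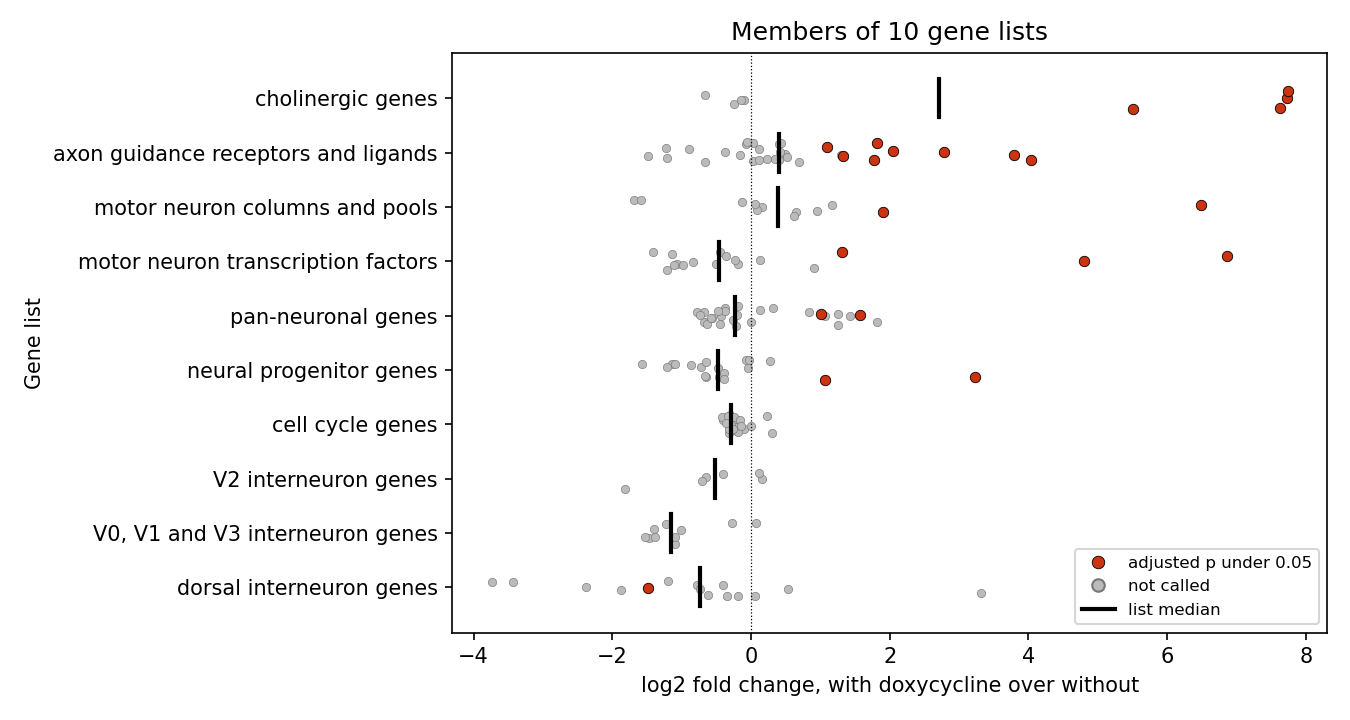
Log2 fold change with Dox over without Dox of each tested member of 10 gene lists; each point is a gene, red where its adjusted p was under 0.05, and the black bar is the list median. The median lay at 2.70 for cholinergic genes and at -1.16 for V0, V1 and V3 interneuron genes.

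Genes shared by most neurons did not pass the set test. Of 28 pan-neuronal genes, edgeR called 2 higher and 26 neither way, DESeq2 6 higher and 1 lower, limma-voom 3 higher, and edgeR with library totals or with no filter 5 higher. With a library left out edgeR called 3 to 6 higher and 0 to 2 lower. With adjustment over this list only, 6 were higher and 2 lower. A block on the replicate number gave 6 higher and 10 lower. The neurofilament gene Nefm rose by log2 1.57 (SE 0.14, adjusted p = 0.00758) and Gap43, a growth cone protein, from 22.0 and 24.6 CPM to 47.8 and 45.7 CPM (adjusted p = 0.0267). The list had a median of -0.23, a mean of 0.09 and a set test adjusted p = 0.549. Without Dox replicate 2 the pan-neuronal set test passed in the direction of a rise (adjusted p = 0.0136; 0.757 with an estimated correlation), while the median was -0.03, as it was without no Dox replicate 1; it was -0.37 without no Dox replicate 2 and -0.45 without Dox replicate 1. None of 23 synaptic vesicle and active zone genes was called by edgeR, DESeq2 or limma-voom. Syt11 and Vamp2 had log2 fold changes of -0.45 and 0.15, and the synaptic list an adjusted p = 0.64 (0.0483 without Dox replicate 1, and 0.657 there with an estimated correlation). Neural progenitor genes were lower as a list (camera adjusted p = 0.0143, median -0.47; adjusted p = 0.685 with an estimated correlation). Of its 19 members, edgeR called 2 higher and none lower, DESeq2 2 higher and 4 lower, and limma-voom 2 higher, while edgeR called 3 lower with no filter and 8 lower without Dox replicate 1. Within the list alone, 2 were higher and 6 lower after adjustment. The 2 higher ones in the edgeR test were Nkx6-2, a homeodomain factor of ventral progenitors, by log2 3.23 (SE 0.24, adjusted p = 0.0039) and Sox9 by 1.07 (SE 0.16, adjusted p = 0.0448). The call for Sox9 ended when only genes with a mean of 5 CPM were tested (adjusted p = 0.0585), and so did that for the list (0.0523). The call for the progenitor list ended without no Dox replicate 1 (median -0.31, adjusted p = 0.204) and without Dox replicate 2 (median -0.20, adjusted p = 0.368), and its median was -0.72 without no Dox replicate 2 and -0.86 without Dox replicate 1.

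Cell cycle genes were lower as a list by a small amount (camera adjusted p = 8.14e-05, median -0.28, and adjusted p = 0.456 with an estimated correlation). Of 27 members 25 lay below 0, and none was called by edgeR in the main test, DESeq2 or limma-voom. With the replicate number as a block, edgeR called 15 lower and 1 higher. Mki67 stood at 748 and 613 CPM without Dox and at 577 and 513 CPM with it (adjusted p = 0.582), Top2a had a log2 fold change of -0.33 (adjusted p = 0.669) and Ccnd2 one of 0.30 (adjusted p = 0.754). Notch pathway genes, of which edgeR called 0 of 17 and DESeq2 3 lower, had a median of -0.20 (camera adjusted p = 0.0123; adjusted p = 0.664 with an estimated correlation). Without Dox replicate 1 the Notch list had 5 members lower (median -0.30, adjusted p = 4.05e-06). The Notch call ended without no Dox replicate 1 (median -0.10, adjusted p = 0.225) and without Dox replicate 2 (median -0.09, adjusted p = 0.226), and the median was -0.34 without no Dox replicate 2. Notch1, Notch2 and Notch3 had log2 fold changes of -0.27, 0.07 and 0.09. Hedgehog pathway genes had a median of -0.03 (adjusted p = 0.64), with Smo at -0.04, Ptch1 at 0.08 and Gas1 at -0.01, and of the 12 edgeR called none and DESeq2 2 higher and 1 lower.

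Retinoid pathway genes changed in both directions, with 2 of 17 higher and 1 lower by edgeR and 4 higher and 3 lower by DESeq2. Rxrg, a retinoid X receptor, went from 0.367 and 0.490 CPM to 6.48 and 8.61 CPM (log2 fold change 4.14, SE 0.33, adjusted p = 0.00421). Aldh1a3, which makes retinoic acid, went from 3 counts to 103 (ratio 19.3, 95% counting interval 6.43 to 95.2, adjusted p = 0.0425). Its log2 change of 4.15 became 4.78 without no Dox replicate 2, and its call ended without no Dox replicate 1 (adjusted p = 0.0688). With the largest part of each gene as its count, the calls for Rxrg (0.0707) and Aldh1a3 (0.148) ended. Crabp1, which binds retinoic acid in the cytoplasm, was the member that fell. The retinoid list had a median of 0.12 (set test adjusted p = 0.181). Of 26 Hox genes tested, edgeR called none and DESeq2 1 lower. Hoxb3, Hoxc5 and Hoxb8 stood between 47.9 and 101 CPM in all 4 libraries, with log2 fold changes of -0.09, 0.14 and -0.50. The Hox list had a median of -0.16 and an adjusted p = 0.102, which became 0.0169 without no Dox replicate 2 and 0.000218 without Dox replicate 1 (0.733 and 0.558 with an estimated correlation). Its median was -0.02 without no Dox replicate 1 and 0.03 without Dox replicate 2. Without Dox replicate 1, 2 Hox genes were called lower, among them Hoxb8 (adjusted p = 0.0299).

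Markers of other cell types that such aggregates can hold were read with the same fit. Mesoderm, endothelial and fibroblast markers were higher as a list (camera adjusted p = 1.09e-05, median 0.47; adjusted p = 0.456 with an estimated correlation). The collagen genes Col3a1 (log2 fold change 2.24, SE 0.17, adjusted p = 0.004) and Col1a1 (2.00, SE 0.23, adjusted p = 0.0175) were its 2 called members of 13 in edgeR, while DESeq2 and limma-voom called 3 higher, and edgeR 3 or 4 with a library left out. Its median was 0.30 without no Dox replicate 1 and 0.26 without Dox replicate 2. Of 13 endoderm markers, Apob rose (1.87, SE 0.26, adjusted p = 0.0363) and 12 were not called, with a median of -0.02, a mean of 0.22 and an adjusted p = 0.64. With the largest part of each gene as its count, the calls for Col1a1 (0.0666) and Apob (0.121) ended. Of 9 glial markers, Aqp4, a water channel, rose (4.36, SE 0.36, adjusted p = 0.00489), DESeq2 called 1 higher and 1 lower, and the list had a median of -0.08, a mean of 0.31 and an adjusted p = 0.549. Neural crest markers, 0 of 7 called by edgeR, had a median of -0.18 (adjusted p = 0.077), and one of -0.06 without no Dox replicate 2 and -0.03 with no filter. Tfap2b had a log2 fold change of -1.08 (SE 0.18, adjusted p = 0.0615) and was called by DESeq2 (4.77e-05), with library totals (0.0412), with no filter (0.0168) and with any 1 library left out (adjusted p between 0.000943 and 0.0376), while Ets1 and Tfap2a had changes of -0.18 and -0.26. Floor plate markers, 0 of 7 called by edgeR, had a median of -0.59 (adjusted p = 0.0903), and one of -0.18 without no Dox replicate 1, -0.94 without no Dox replicate 2 and -0.39 without Dox replicate 2. The floor plate list passed without no Dox replicate 2 (0.00709), without Dox replicate 1 (0.0343), after thinning (0.0486) and with the largest part as the count (0.0259), and in none of these with an estimated correlation (0.392 to 0.693). Ntn1 had a log2 fold change of -0.90 (adjusted p = 0.186; 0.0104 in DESeq2, 0.00778 without no Dox replicate 2 and 0.0176 without Dox replicate 1), Spon1 one of -0.59 (adjusted p = 0.574; 0.0387 without no Dox replicate 2), and Foxa2 one of 0.04. Pluripotency genes had a median of 0.16 (mean 0.12, adjusted p = 0.96), and Klf4, Lin28a and Tfcp2l1 had changes of -0.25, -0.16 and -0.10. Only 2 blood markers could be tested, Cd34 (0.37) and Runx3 (-0.28), too few for a set test.

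Among stress lists, heat shock and immediate early genes were higher (camera adjusted p = 0.00036, median 0.39; adjusted p = 0.456 with an estimated correlation), with 1 of 15 called by edgeR and 4 called higher by DESeq2 and by edgeR without Dox replicate 1. The edgeR call was Jun, at 53.1 and 48.8 CPM without Dox and 155 and 150 CPM with it (log2 fold change 1.58, SE 0.11, adjusted p = 0.00351). Adjusted over the list alone, 6 were higher. The median was 0.12 without no Dox replicate 1, 0.11 without Dox replicate 2, and 0.70 without no Dox replicate 2. Genes of p53 and apoptosis (median 0.02, adjusted p = 0.96) and of the integrated stress response (median -0.05, adjusted p = 0.428) had no member called by edgeR, DESeq2 or limma-voom. Trp53inp1, Mdm2 and Ccng1 had log2 fold changes of 0.32, -0.04 and 0.00, and Psat1, Asns and Atf4 had changes of -0.42, -0.27 and 0.02. None of the 15 genes of the mitochondrial genome matched a gene unit, so that list could not be tested. Over the 12 lists beyond the interneuron ones with no edgeR call, 6 of 168 members were higher and 26 lower at an unadjusted p under 0.05. DESeq2 called 2 higher and 7 lower, and limma-voom 0.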

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

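The report's comparisons use counts summed over each gene. The separate part counts, which they do not use, were tested for uneven change along genes; of the tests below, those of shared Slit reads and of the Isl1 and Lhx3 parts were chosen only after the result was seen. The same holds for the condition that a transcript starting inside a Slit gene must reach the last exon; the annotated starts alone met the bound set before. The bound of the full-length Isl1 and Lhx3 tests was also replaced after their values were seen. The first one set the rise of the last part against that expected for the whole exon, where a ratio below 0.25 argued against full-length transcripts and one from 0.5 up for them; it gave 0.112 for Isl1, which argued against them, and 0.349 for Lhx3, which it left undecided. It was replaced because 416 of the 1296 bases of Lhx3's last exon are coding, so a rise of coding sequence alone lifts that ratio above the bound; the verdict for Lhx3 below rests on the second bound (under 0.5 of the lowest coding part). By the gene-level F test, 4 of 11556 genes used their parts differently with Dox: Slit2 (adjusted p = 2.9e-09), Slit3 (1.75e-05), Lars2 (9.52e-05) and Gnas (0.0112). By the Simes test 2 did, Slit2 (2.8e-09) and Gnas (0.000282). Neither test called Isl1 (0.582 by F and 1 by Simes) or Lhx3 (1 by both), so their pattern below rests on values per part and on intervals that cover counting error only. At an unadjusted p under 0.05 the F test gave 63 genes where 578 would be expected with no effect, so its p-values run too high here. In Lars2 the last part held the difference, at 148 and 61.2 CPM without Dox and 36.4 and 53.04 CPM with Dox.

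In both Slit genes most of the rise with Dox lay from the sixth of 36 parts on, where counts rose 18.3-fold in Slit2 and 7.35-fold in Slit3, while the first 4 parts differed 1.47-fold and 0.994-fold and the fifth 3.77-fold (log2 change 1.91, counting interval 1.35 to 2.52) and 0.843-fold. A shift of coverage towards gene ends with Dox would move parts of other genes too. Over 1945 other genes with at least 20 parts, the median change of higher-numbered over lower-numbered parts was 0.0149 on the log2 scale. Genes of both strands were pooled, and on the minus strand, as in Isl1 and Lhx3, part 1 holds the last exon. A shift could therefore cancel in that median, which does not decide. It would still widen the spread, but the SD was 0.23 and the highest other gene reached 1.67. Slit2 stood at 3.64 and Slit3 at 2.88, so the spread argues against a general shift of that size. Reads shared between the paralogs would leave unlike parts unmoved, but the last part of Slit3, which holds its 3' untranslated region, changed by 2.79 (counting interval 2.43 to 3.17). Transcripts that start inside both genes could give such a rise, and the later annotation lists 4 whose first exon lies between exons 4 and 7 of the full-length transcript, 3 of 23 in Slit2 and 1 of 4 in Slit3. As annotated these hold 8, 6 and 1 exons in Slit2 and 9 in Slit3, and 0 of them reach the last exon, so they do not account for a rise up to part 36 and the explanation stays open.

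The microRNA gene Mir218-2, which lies inside Slit3, had 0 counts in both libraries without Dox and 85 and 126 with Dox, at least 39.6-fold higher against a floor of 3 counts over the group (adjusted p = 0.0127), and was chosen after its values were seen. Mir218-1, inside Slit2, had 0 and 0 counts without Dox and 5 and 3 with Dox. Whether these reads come from the microRNA precursors or from unspliced Slit transcripts stays open.

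The rise of Isl1 and Lhx3 per kb was highest in wholly coding parts. If full-length transcripts rose as much as the coding parts, the last part should rise as much per kb, but its rise was 0.159 of the lowest wholly coding part in Isl1 and 0.389 in Lhx3. Part edges raise the density of short parts where a read is counted in each part it spans, but the libraries without Dox, counted alike, put 48.5% of Isl1 counts in the last part (110 of 227, 95% Wilson interval 42.0 to 54.9), beside its 52.3% of exon length, and those with Dox 15.7% (14.9 to 16.5); in Lhx3 the shares were 83.3% without Dox (15 of 18, 60.8 to 94.2), above its 58.3% of exon length, and 38.0% with Dox (37.0 to 38.9). Transcripts that carry only the coding sequence may account for it, as a fusion transgene could: the rise in the last part was 1.29 times what its coding bases alone give in Isl1 and 1.09 times in Lhx3. The labels do not say which untranslated sequence the induced fusion carries, and a smaller rise of the cells' own genes stays open.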

How the results depend on the processing

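Thinning to the smallest total, taking the largest part, and the tests of scaling, depth and replicate number as reasons for the excess of higher genes were chosen only after the result was seen, and so were the conditions that leave scaling and replicate number open below. Beside 175 higher and 8 lower genes (167 and 6 at 2-fold), library totals alone gave 16 lower (14 at 2-fold), no filter 294 higher and 45 lower (37 lower at 2-fold), a mean of 5 CPM 104 and 4 (103 higher at 2-fold), DESeq2 398 and 113 (291 and 71 at 2-fold), limma-voom 13 lower (11 at 2-fold), the largest part 14 lower, and a threshold of 0.01 gave 75 and 2 (75 and 2 at 2-fold). Fewer genes were tested at 5 CPM; the cause of the other differences was not tested. With each library left out, 276 to 284 were higher and 22 to 124 lower (230 to 270 and 19 to 104 at 2-fold). Calls of the main test were mostly kept, while several alternatives called many more: of the 175, between 132 (largest part) and 175 were called higher in each alternative except the 5 CPM filter, which kept 104, and the threshold of 0.01, which kept 75.

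Replicate numbers are shared between the groups, but no label says what a number marks. Libraries of one number deviated together (correlation across genes 0.52, 2 pairs). With the number as a block, 1046 genes were higher and 864 lower (426 and 150 at 2-fold). All 183 calls were among them. Lists with few or no single calls gained many. Motor neuron transcription factors had 4 higher and 9 lower, and V2 genes 0 and 3. V0, V1 and V3 genes had 0 and 7, and dorsal interneuron genes 1 and 8. Neural progenitor genes had 2 and 13, and cell cycle genes 1 and 15. Pan-neuronal genes had 6 and 10, Notch pathway genes 1 and 7, Hox genes 0 and 6, and axon guidance genes 15 and 5. By camera at the preset correlation the Hox (adjusted p = 0.0162), neural crest (0.0365) and floor plate lists (0.0162) were lower. With an estimated one none passed. The share of calls that were higher was 95.6% in the main test. It was 93.8% after thinning, which argues against depth as the reason. It was 92.7% with library totals, but that setting moved the median log2 change of all genes by only 0.0227, too little to test scaling, which stays open. It was 86.7% with no filter, 77.9% in DESeq2, 76.8% without no Dox replicate 2, 69.6% without Dox replicate 1, and 92.0% and 92.6% without the other 2 libraries, all settings with more calls of both directions. It was 54.8% with the block, which added 871 higher and 856 lower calls and left higher minus lower at 182 beside 167, so whether shared spread accounts for the excess may be read either way and stays open, as does a biological excess of rises.

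The motor neuron transcription factor list passed with a mean of 5 CPM (median -0.892, 12 of 17 genes tested, without Lhx4, its largest rise; adjusted p = 0.793 with an estimated correlation). No list passed with an estimated correlation in any alternative. With so few libraries that version also missed the simulated list moved 2-fold, so its failures do not show that a list was unmoved. The V2 list had a median of -0.132 in DESeq2 and -0.117 with no filter, where more genes enter, and -0.641 to -0.408 with each library left out. At 5 CPM the 3 interneuron lists kept fewer than 5 genes each and were not tested. Cholinergic, V0, V1 and V3 and dorsal lists kept direction and call, with the preset correlation, in every alternative that tested them. Of 1360 other values compared, 1230 kept direction and side, 25 lost their call, 45 gained one, 58 changed sign, and 2 list medians without a set test moved in DESeq2 (pluripotency -0.096, neural crest -0.051). None of the 58 passed the threshold either way, and the cause was not tested. Log2 changes on the other side of 0 were, for the largest part, Gata3 -0.080, Slc6a9 -0.100, Tfcp2l1 0.051, Ccng1 -0.015, the p53 list -0.015 and the synaptic list 0.021. After thinning they were Atf4 -0.012, Ccng1 -0.007, Cd34 -0.063, Gas1 0.010 and the glial list 0.193. Gas1 was 0.011 with library totals, 0.009 with no filter and 0.002 at 5 CPM. The pluripotency list was -0.077 with no filter and -0.084 at 5 CPM, the Hedgehog list 0.002 at 5 CPM, and the endoderm list 0.051 in limma-voom and 0.025 with the block. With each library left out, the ranges that crossed 0 were Atf4 -0.179 to 0.207, Ccng1 -0.087 to 0.108, Cd34 -0.432 to 0.843, Foxa2 -0.241 to 0.306, Gas1 -0.092 to 0.077, Gata3 -0.066 to 0.336, Hoxb3 -0.241 to 0.060, Mdm2 -0.110 to 0.031, Notch1 -0.704 to 0.163, Notch2 -0.210 to 0.423, Notch3 -0.219 to 0.479, Ptch1 -0.361 to 0.711, Runx3 -0.714 to 0.369, Smo -0.201 to 0.123 and Tfcp2l1 -0.391 to 0.277. For lists they were Hedgehog -0.262 to 0.094, Hox -0.227 to 0.028, endoderm -0.056 to 0.163, transmitter -0.297 to 0.185, glial -0.258 to 0.172, p53 -0.085 to 0.136, pluripotency -0.146 to 0.327 and synaptic -0.301 to 0.182. Depth limits genes such as Chat, Lhx4 and Chodl, whose controls hold 4 counts, in the size of their change and not in its direction.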

Other observations

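Col4a1, Col4a2, Lama1, Sparc, Lamc1 and Lamb1, which encode proteins of the basement membrane, had the highest mean CPM of all genes tested, and none of them was called. These 6 genes were chosen after their values were seen. Col4a1 stood at 23466 and 22244 CPM without Dox and at 22289 and 24712 CPM with Dox (log2 fold change 0.04, SE 0.15, adjusted p = 0.983). Of the endoderm list, which was fixed beforehand, 3 abundant members that were not called were picked after their values were seen. Dab2 stood at 706 and 809 CPM without Dox and at 647 and 745 CPM with Dox, Gata4 at 560 and 591 and at 553 and 644 CPM, and Sox17 at 92.7 and 109 and at 86.8 and 86.0 CPM. By comparison, Mnx1 reached 48.5 and 43.9 CPM and Chat 18.1 and 16.4 CPM with Dox.

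Several called genes outside the lists had few or no control counts. Tm4sf4 went from 0 counts to 122 with Dox, at least 22.9-fold higher against a floor of 3 counts over the group (adjusted p = 0.0262). Ptgdr, a prostaglandin receptor, went from 1 count to 418 (ratio 235, 95% counting interval 42.0 to 9310). Uts2b, a urotensin-related peptide, went from 3 counts to 187 (ratio 35.1, 95% counting interval 11.8 to 172). They too were chosen after their values were seen.

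Replicate 1 over replicate 2 correlated with transcript length across 14073 genes, with a Spearman rho of 0.478 without Dox and 0.341 with Dox, while the change with Dox had a rho of 0.056. Genes are not independent replicates, so no p is given.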
